A study of Arabidopsis thaliana with 18 samples.

How the data were processed

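Gene expression was measured in leaves and roots of hydroponically grown Arabidopsis thaliana Columbia-0 with Affymetrix ATH1 arrays, 18 in all, 3 biological replicates for each of 6 groups, per the labels' protocols. The groups were mock, osmotic (0.3 M mannitol for 3 h in the light) and day 11 plants of each organ. Per the labels' protocols, some stressed plants were returned to basal medium for 1 day, taken here as the day 11 groups. Those protocols label and hybridise total RNA as the array manufacturer's manual describes.

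The table held log2 expression values that the authors had deposited, 1 column for each array and 22810 probe sets. The method by which the authors summarised and normalised the arrays was not given in the sources used here. The log base was read from the values, which ran from 2.38 to 13.9. The upper end lies above 11.1, the natural logarithm of the highest 16-bit intensity, and below 16, its base 2 logarithm. Array medians lay between 6.553 and 6.69, so the arrays had been brought to one scale, and the values were not centred for each gene. They were used as deposited, without floor or further normalisation, and every column of the table was assigned to a group.

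The 64 control probe sets of the manufacturer were left out, which left 22746. The platform annotation supplied paired 13513 of these with 1 gene, 503 with several genes and 8730 with none, and 13436 of the former were matched to the RefSeq gene table by their gene identifier (77 were not). Counts of changed probe sets cover all 22746, whereas named genes and gene lists use the 13356 genes with a probe set of their own, 1535 of them with a symbol other than the locus name. Where a gene had several probe sets, the probe set with the highest mean over all arrays was used. No genome build was named with the array values, so no coordinates are given.

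A linear model with a mean for each of the 6 groups was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend. The 9 comparisons were osmotic against mock, day 11 against mock and day 11 against osmotic in each organ, the root minus leaf difference of the osmotic and of the day 11 response, and mock roots against mock leaves. The p-values were adjusted by the Benjamini-Hochberg method over all probe sets of a comparison, and an adjusted p threshold of 0.05 defined a change. With 3 arrays against 3, the smallest two-sided exact permutation p is 0.1, so a single value compared without the model cannot pass that threshold. No sequencing depth applies to arrays. Precision is given by the spread among replicates, and the median SD of a probe set within groups was 0.124 to 0.174.

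Gene lists were fixed before the data were examined, together with the comparisons, the rule for named genes and the alternatives: 22 lists with 402 members, of which 45 had a probe set of their own (88.8% were lost to the annotation). Therefore 19 lists with 332 members were added from the genes that the annotation does name, after it was read but before any expression change was computed. The 26 lists with at least 3 measured members were tested with camera of limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Members of the lists fixed first were also adjusted over their list alone. The rule for named genes took, for each comparison with mock, the 6 largest rises and the 6 largest falls among genes that passed the adjusted p threshold, changed at least 2-fold, had no overlap between the arrays of both groups and lay above 6.61, the median of all values, in the brighter group. For each list it took up to 4 members past the threshold with the largest change and up to 2 others, and for the remaining comparisons the 4 largest in each direction by the same criteria.

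The fit was tested on simulated data with real spreads. In 1 comparison at a time, 200 of 22746 probe sets changed by log2 0.5, 1 or 2. Far more probe sets changed in the osmotic comparisons (4694 and 5523), so the rates need not hold there. At 0.5 it found 40.3%, 28.4% and 26.9% of the changes in leaves (osmotic against mock, day 11 against mock and day 11 against osmotic). Roots gave 40.3%, 26.9% and 28.4%. The organ differences of the osmotic and day 11 response gave 7.46% and 2.99%, and mock roots against mock leaves 23.9%. At 1 it found, in the same order, 83.6%, 91%, 94%, 89.6%, 89.6%, 94%, 68.7%, 68.7% and 85.1%. At 2 it found 100%, but 95.5% for the organ difference of the day 11 response and 98.5% for mock roots against mock leaves. False calls were 1.91% to 8.62% of all calls. Lists of 20 genes shifted by 0.5 had camera p-values of at most 3.7e-14, and unchanged lists of at least 0.13. Simulated genes were independent, so the preset correlation was not tested.

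Overlaps between comparisons sharing the mock arrays were set against 20 simulations without group differences. Moves back from the osmotic state were set against 20 with day 11 values drawn around the osmotic means. The RNA quality signs available were the control probe sets of both ends of the actin, GAPDH and ubiquitin transcripts, and the exact permutation p of their difference between a treatment and mock was 0.1 or more in each case. The alternatives tried were quantile normalisation over all arrays and within each organ, centring each array on its median, leaving out dim probe sets, eBayes without the trend, array weights, the arrays of a comparison alone, the replicate number as a block, a threshold of 0.01, at least a 2-fold change, an estimated correlation for the lists, and leaving out each array. List member counts with 1 array left out were compiled from these planned fits after the results were seen. Moves beyond 1.5 times were kept.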

Results

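Leaves and roots of Arabidopsis thaliana accession Columbia-0 were profiled on 18 Affymetrix ATH1 arrays, which measure transcript abundance with probe sets. The arrays formed 6 groups of 3 biological replicates, a number that limits the precision of every change given. In each organ there were mock plants, plants exposed to 0.3 M mannitol in the hydroponic medium for 3 h in the light (osmotic), and plants with the label of day 11. The day 11 groups were taken as the stressed plants that the treatment description moves back to basal medium for 1 day. The labels name day 10 and day 11, the description plants of 30 days, so the age was left open. All mock and osmotic plants carried the day 10 label, so day 11 differences also hold a day of age and the transfer. The sampling hour of the mock plants was not given in the sources used here. The values were the log2 expression values that the authors deposited. The correlation across probe sets between arrays of one group was 0.9867 to 0.9947, with probe sets not being independent replicates. Changes are differences of group means on the log2 scale ± SE from a limma fit over all arrays, and the p-values are Benjamini-Hochberg adjusted. For every gene named for the size of its change, the 3 arrays of one group lay above the 3 arrays of the other. Detection calls were not used here. Where the lower of both group means lay below the lower quartile of the arrays (4.268 to 4.496), it was not separated from background, so that the log2 change is at best a lower bound and its rank is not fixed. Among others, that held for COR27, AT4G33980, AT5G28520, scpl30, BGLU24, AT1G32970, AT2G26380, PR-1-LIKE, AT1G26250, AT3G01190 and PRK. A ceiling of the QQS probe set was neither shown nor excluded, so its changes may be only lower bounds too. When the responses of the organs were compared, a fall in 1 organ that would take the mock mean of the other below 4.496 could not be seen there in full, and such differences are called limited by the background.

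The comparison of mock roots with mock leaves showed how the organs differed without stress. Photosynthesis transcripts were far lower in roots. All 27 nuclear photosynthesis and chlorophyll genes were lower, with a median of -5.77 (camera adjusted p = 4.8e-22; adjusted p = 0.076 with an estimated correlation), and all 42 plastid-encoded genes were lower, with a median of -3.25 (adjusted p = 7.9e-21; adjusted p = 0.1 with an estimated correlation). PRK (AT1G32060), the phosphoribulokinase of carbon fixation, was at -8.49 ± 0.16, and PSAE-1 (AT4G28750) of photosystem I at -8.41 ± 0.25. The 3 measured leaf markers were lower, all 3 also when adjusted over the list alone (median -7.07, adjusted p = 0.00037; adjusted p = 0.12 with an estimated correlation). The 3 measured root markers were higher, all 3 also when adjusted over the list alone (median 4.09, adjusted p = 0.0079; adjusted p = 0.1 with an estimated correlation), among them the root hair expansin EXPA7 (AT1G12560) at 4.77 ± 0.17. AT1G26250, of the extensin family of wall proteins, was higher in roots by 9.03 ± 0.17, and the peroxidase AT3G01190 by 8.95 ± 0.12. Of 26 genes of xylan synthesis and wall acetylation, 16 were higher and 3 lower in roots (adjusted p = 0.013; adjusted p = 0.1 with an estimated correlation), and 6 of 8 flavonoid genes were lower (adjusted p = 0.00032; adjusted p = 0.1 with an estimated correlation). Of 11 expansins and xyloglucan endotransglucosylases, 9 were higher and 2 lower, with the same counts when adjusted over the list alone (adjusted p = 0.045; adjusted p = 0.23 with an estimated correlation). That call ended without mock leaf replicate 1 (adjusted p = 0.054) and without mock root replicate 3 (adjusted p = 0.05), and when dim probe sets were left out (adjusted p = 0.11). In all, 12853 of 22746 probe sets (56.5%) differed, 7617 higher and 5236 lower in roots.

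The comparison of osmotic with mock leaves asked how leaf transcripts responded to mannitol. Protective proteins of dehydration and abscisic acid (ABA) responses rose together: all 5 measured members rose, all 5 also when adjusted over the list alone, with a median of 2.06 (camera adjusted p = 1.2e-08; adjusted p = 0.0017 with an estimated correlation). LEA4-5 (AT5G06760), a late embryogenesis abundant protein, rose by 2.88 ± 0.22 (adjusted p = 1.9e-07), the dehydrin LTI30 (AT3G50970) by 2.30 ± 0.24, and the chloroplast stress protein COR15A (AT2G42540) by 2.06 ± 0.23. The largest rises of single named genes were those of COR27 (AT5G42900), a cold-regulated gene of light and clock signalling, from a mean of 4.099 to 8.116 (4.02 ± 0.25, adjusted p = 3.2e-08), and of AT3G02480, of the late embryogenesis abundant family, by 3.90 ± 0.39. QQS (AT3G30720), an orphan gene linked to starch content, rose by 3.48 ± 0.29, AT4G33980, related to COR27, by 3.42 ± 0.30, the U-box ubiquitin ligase PUB19 (AT1G60190) by 3.22 ± 0.23, and AT2G41190, of an amino acid transporter family, by 3.08 ± 0.23. Of named genes, the wall-loosening expansin EXPA8 (AT2G40610) fell most, by 3.42 ± 0.35 (adjusted p = 3.6e-06). Next, the lipase-like AT1G29660 fell by 2.90 ± 0.35 and the acid phosphatase-like AT5G44020 fell by 2.83 ± 0.24. The transcription factor BZIP61 (AT3G58120) fell by 2.67 ± 0.37 and the glutaredoxin AT1G06830 fell by 2.65 ± 0.38.

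Several other gene groups rose in osmotic leaves. All 3 senescence genes rose, all 3 also when adjusted over the list alone (adjusted p = 0.00036; adjusted p = 0.03 with an estimated correlation), with WRKY53 (AT4G23810) at 1.90 ± 0.27. Of 14 further drought- and ABA-induced genes, 7 rose and 1 fell (adjusted p = 0.00014; adjusted p = 0.03 with an estimated correlation). XERICO (AT2G04240), a RING protein of ABA accumulation, rose by 0.92 ± 0.14, and HVA22C (AT1G69700) fell by 0.59 ± 0.15. Of 10 autophagy genes, 9 rose (adjusted p = 1e-05; adjusted p = 0.17 with an estimated correlation), including ATG8D (AT2G05630) by 0.79 ± 0.15. Of 9 genes of branched-chain amino acid breakdown, 6 rose (adjusted p = 0.0022; adjusted p = 0.23 with an estimated correlation). Of 13 genes of ER stress and quality control, 4 rose (adjusted p = 0.0035; adjusted p = 0.3 with an estimated correlation), among them UBC32 (AT3G17000) by 1.16 ± 0.14. Of 9 U-box ubiquitin ligases, 3 rose (adjusted p = 0.0059; adjusted p = 0.19 with an estimated correlation), PUB24 (AT3G11840) by 1.18 ± 0.27. Of 43 family 1 glycosyltransferases, 9 rose and 2 fell (adjusted p = 0.0059; adjusted p = 0.3 with an estimated correlation). STZ (AT1G27730), a zinc finger transcription factor of stress responses, rose by 1.12 ± 0.19. The counts of list members moved with single arrays: without mock leaf replicate 2, 4 autophagy and 2 ER stress genes rose, without osmotic leaf replicate 2, 5 autophagy genes and 5 glycosyltransferases, and without osmotic leaf replicate 3, 3 genes of branched-chain amino acid breakdown.

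Photosynthesis and ribosome biogenesis transcripts fell in osmotic leaves. Of 27 nuclear photosynthesis and chlorophyll genes, 12 fell and 1 rose, with a median of -0.44 (adjusted p = 0.00014; adjusted p = 0.3 with an estimated correlation). The thylakoid calcium-sensing protein gene CaS (AT5G23060) fell by 1.13 ± 0.25 and the Calvin cycle gene SBPASE (AT3G55800) fell by 0.92 ± 0.15. Of 42 plastid-encoded genes, 10 fell and 0 rose, with a median of -0.16 (adjusted p = 0.0071; adjusted p = 0.55 with an estimated correlation). Without mock leaf replicate 2 or without osmotic leaf replicate 1 the adjusted p of the plastid-encoded list was 0.07 and 0.24. Its falling members were 5 without mock leaf replicate 1 or osmotic leaf replicate 1 and 6 without osmotic leaf replicate 2, which also left 6 falling nuclear photosynthesis genes, and the rising nuclear gene lost its call without mock leaf replicates 2 or 3 or osmotic leaf replicates 2 or 3. Of 10 genes of ribosome biogenesis and RNA polymerases I and III, 6 fell (adjusted p = 0.0035; adjusted p = 0.18 with an estimated correlation), among them NRPA1 (AT3G57660), the largest subunit of RNA polymerase I, which fell by 0.76 ± 0.15. The cytokinin response regulators ARR15 (AT1G74890) and RR16 (AT2G40670) fell by 1.14 ± 0.21 and 1.64 ± 0.26. None of the 3 leaf markers (camera adjusted p = 0.73) and none of the 3 root markers (adjusted p = 0.88) passed the test, nor did any when adjusted over the list alone. In all, 4694 of 22746 probe sets (20.6%) changed, 1960 upwards and 2734 downwards, of which 648 rose and 408 fell at least 2-fold. Centring each array on its median gave 2514 rises and 2097 falls, a share of rises of 54.5% beside 41.8%, and with the mock and osmotic leaf arrays alone in the fit 3063 probe sets changed. Without osmotic leaf replicate 2 the count was 3048.

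The comparison of osmotic with mock roots asked the same of the organ in contact with mannitol. The largest rises were of transcripts whose mean in mock roots lay below 6.61, the median of all values. AT5G28520, of the jacalin lectin family, rose from a mean of 4.109 to 10.85 (6.74 ± 0.25, adjusted p = 3.6e-12), and its neighbouring locus BGLU24 (AT5G28510), a beta-glucosidase, rose by 6.29 ± 0.24. The carboxypeptidase-like scpl30 (AT4G15100) rose by 6.33 ± 0.24, the subtilase AT1G32970 by 5.86 ± 0.19, QQS by 5.35 ± 0.29 and the leucine-rich repeat protein AT2G26380 by 5.03 ± 0.17. AT1G73600, of the phosphoethanolamine methyltransferases of phospholipid synthesis, fell most, by 4.66 ± 0.36 (adjusted p = 2.9e-08). Next, AT1G07690 fell by 4.14 ± 0.19 and the receptor kinase AT5G37450 fell by 3.78 ± 0.29. AT3G46880 fell by 3.71 ± 0.31, and PR-1-LIKE (AT2G19990) fell by 3.6 ± 0.24.

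Among the gene groups, 3 of 5 dehydration and ABA-responsive proteins rose in osmotic roots, the same 3 when adjusted over the list alone, with a median of 1.03 (camera adjusted p = 0.00086; adjusted p = 0.061 with an estimated correlation). LEA4-5 rose by 4.51 ± 0.22, LTI30 by 2.85 ± 0.24 and COR47 (AT1G20440) by 1.03 ± 0.13, while COR15A stood at 0.29 ± 0.23 (adjusted p = 0.41) and COR15B (AT2G42530) at -0.01 ± 0.21 (adjusted p = 0.98). All 4 touch-inducible genes rose, all 4 also when adjusted over the list alone, with a median of 2.00 (adjusted p = 0.00086; adjusted p = 0.15 with an estimated correlation). The list marks handling, which was not separated from mannitol. The calmodulin-like genes CML38 (AT1G76650), CML37 (AT5G42380) and AT1G76640 rose by 2.46 ± 0.33, 2.26 ± 0.35 and 1.74 ± 0.23. The other 24 lists did not pass the test. Of 11 expansins and xyloglucan endotransglucosylases, 2 rose and 5 fell, or 3 and 6 when adjusted over the list alone (adjusted p = 0.24). EXPA4 (AT2G39700) fell by 1.95 ± 0.19 and EXPA15 (AT2G03090) fell by 1.44 ± 0.22, whereas the endotransglucosylase XTH20 (AT5G48070) rose by 1.30 ± 0.22. AT3G02480 rose by 3.35 ± 0.39, COR27 by 3.17 ± 0.25, the glutathione transferase GSTU25 (AT1G17180) by 2.71 ± 0.35, STZ by 1.68 ± 0.19 and the alternative NADH dehydrogenase NDB2 (AT4G05020) by 1.51 ± 0.27. Of the 3 leaf markers, the rubisco activase gene RCA (AT2G39730) fell by 1.03 ± 0.18, and 2 fell when adjusted over the list alone (camera adjusted p = 0.18). No root marker passed either way (adjusted p = 0.72). In all, 5523 of 22746 probe sets (24.3%) changed, 2411 upwards and 3112 downwards, of which 955 rose and 729 fell at least 2-fold. Centring each array on its median gave 3227 rises and 2365 falls, a share of rises of 57.7% beside 43.7%.

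**Figure D1:**
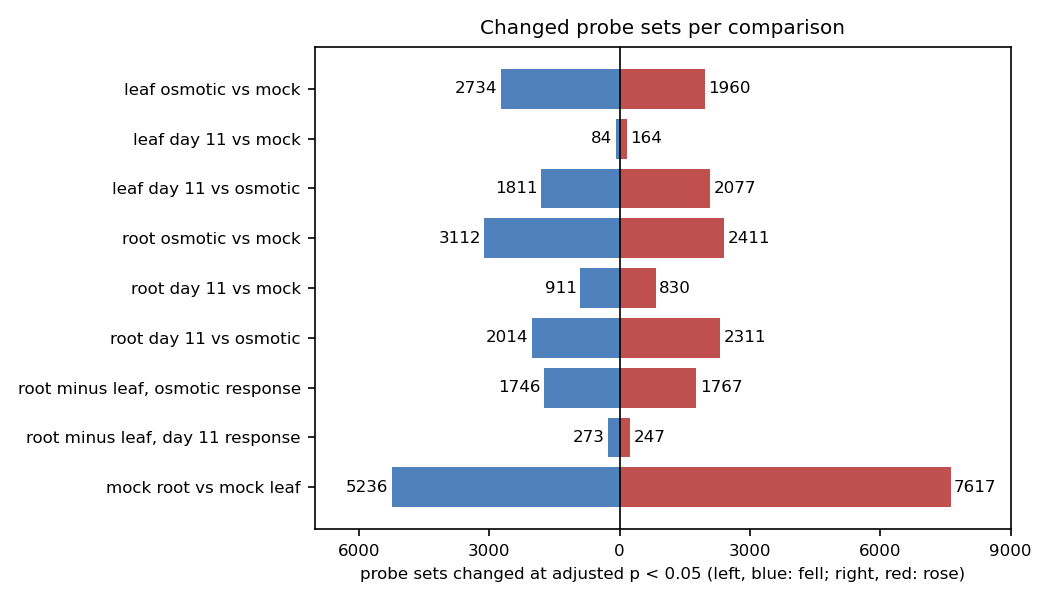
Number of probe sets that rose (right, red) or fell (left, blue) in each of the 9 comparisons at an adjusted p threshold of 0.05 (limma). The 2411 rises and 3112 falls of osmotic roots and the 1960 and 2734 of osmotic leaves stand against 830 and 911 in day 11 roots and 164 and 84 in day 11 leaves.

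The difference between the root and the leaf response to mannitol was tested directly as an interaction. Single genes of sugar transport and dehydration protection responded differently in the organs. The lists did not pass (camera adjusted p = 1 for expansins and endotransglucosylases, with 3 higher and 3 lower of 11, also when adjusted over the list alone; 0.79 for sugar transporters; 0.64 for dehydration, with 1 higher and 2 lower of 5, also when adjusted over the list alone). EXPA8, which fell in leaves, stood at 0.88 ± 0.35 in roots (adjusted p = 0.078; adjusted p = 0.015 with array weights and 0.0064 with the mock and osmotic root arrays alone), where the difference was limited by the background (mock root mean 4.705). The sugar transporter SWEET2 (AT3G14770) fell by 2.08 ± 0.18 in leaves and rose by 0.83 ± 0.18 in roots, a difference of 2.91 ± 0.25 (adjusted p = 5.6e-07). SWEET4 (AT3G28007) rose by 2.26 ± 0.17 in leaves and stood at 0.16 ± 0.17 in roots, a difference of -2.10 ± 0.24 (adjusted p = 1e-05). The response of AT5G28520 was larger in roots by 6.70 ± 0.36 (adjusted p = 1.3e-09) and that of AT1G32970 by 5.89 ± 0.27. The difference was 1.63 ± 0.31 for LEA4-5 (adjusted p = 0.0016), -1.77 ± 0.33 for COR15A (adjusted p = 0.0013) and -1.55 ± 0.20 for XERICO (adjusted p = 4.1e-05), which fell by 0.63 ± 0.14 in roots. For COR27 it was -0.84 ± 0.35 (adjusted p = 0.12), and without osmotic leaf replicate 2 the adjusted p was 0.041. The differences of the cytokinin response regulators ARR15 and RR16 were limited by the background (mock root means 4.771 and 3.611).

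As groups, 6 of 10 ribosome biogenesis genes had a higher response in roots (camera adjusted p = 0.0023; adjusted p = 0.42 with an estimated correlation), with NRPA1 at 0.85 ± 0.21, and so had 4 of 42 plastid-encoded genes (adjusted p = 0.0012; adjusted p = 0.7 with an estimated correlation), psbD among them, with all 4 differences limited by the background. Of 10 autophagy genes, 3 had a lower response in roots (adjusted p = 0.014; adjusted p = 0.57 with an estimated correlation), with APG8A (AT4G21980) at -0.82 ± 0.21. Of 4 touch-inducible genes, 3 had a higher response in roots, the same count as when adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.42 with an estimated correlation). The call of the touch-inducible list ended without mock root replicate 1 (adjusted p = 0.072), mock root replicate 2 (0.06), osmotic leaf replicate 1 (0.076) or osmotic root replicate 2 (0.089), and when dim probe sets were left out (0.076). Its members past the threshold were 1 or 0 without mock leaf replicates 2 or 3, mock root replicates 1 or 2, osmotic leaf replicates 1 or 2 or osmotic root replicate 2. For autophagy they were 1 without mock leaf replicates 2 or 3, mock root replicate 2 or osmotic leaf replicate 2 and 5 without osmotic leaf replicate 1, and for the plastid-encoded genes 2 and 12 without osmotic leaf replicates 1 and 3. The interaction was past the threshold for 3513 probe sets, 1767 with a higher and 1746 with a lower response in roots (1725 and 1847 after quantile normalisation over all arrays). Of these, 569 were limited by the background in leaves and 240 in roots. Of the 1960 probe sets that rose in osmotic leaves, 781 also rose in roots (39.8%; 207.8 if the calls were independent) and 115 fell there (268.2 if independent). Of the 2734 that fell in leaves, 657 also fell in roots (374.1 if independent) and 96 rose (289.8 if independent). The log2 changes of both organs correlated across probe sets with Pearson's r = 0.3945 and Spearman's rho = 0.3242, where probe sets are not independent replicates.

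**Figure D2:**
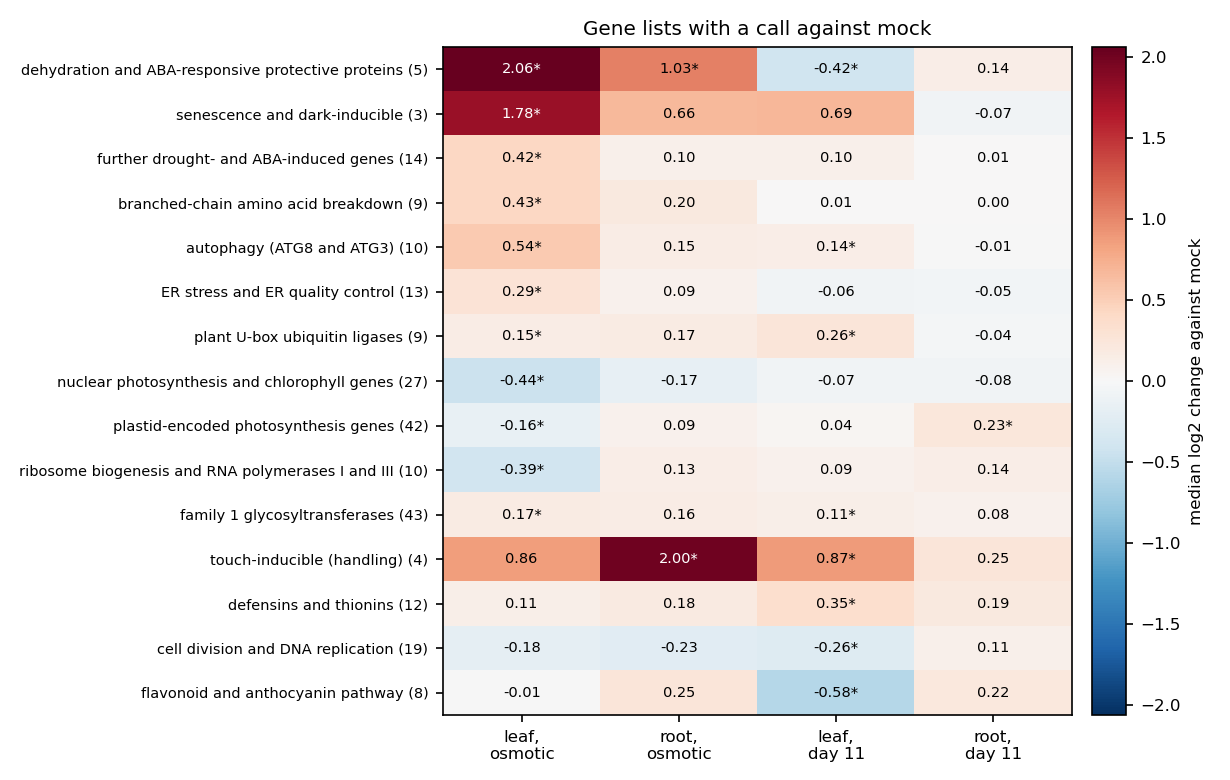
Median log2 change of 15 gene lists against mock (colour) in osmotic leaves, osmotic roots, day 11 leaves and day 11 roots, with the number of measured members in parentheses and an asterisk where camera with a preset correlation passed. The dehydration list stood at 2.06 in osmotic leaves and 1.03 in osmotic roots.

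The comparison of day 11 with mock leaves held recovery, age and transfer together. QQS was still higher than in mock leaves by 3.49 ± 0.29 (adjusted p = 9.2e-06), at 0.00 ± 0.29 from the osmotic leaves. AT4G27654 was higher by 2.49 ± 0.38 (adjusted p = 0.003), AT2G22880 by 1.97 ± 0.26, the growth regulator ARL (AT2G44080) by 1.97 ± 0.26, AT4G29780 by 1.96 ± 0.31 and STZ by 1.41 ± 0.19. DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.92 ± 0.25 (adjusted p = 0.0011), and the neighbouring loci AT1G30250 and AT1G30260 fell by 1.81 ± 0.18 and 1.27 ± 0.14. The expansin EXPA16 (AT3G55500), which had risen by 2.09 ± 0.23 in osmotic leaves, fell by 1.35 ± 0.23 below mock. Of 8 flavonoid and anthocyanin genes, 3 fell, with a median of -0.58 (camera adjusted p = 3.1e-06; adjusted p = 0.075 with an estimated correlation). The call of DFR held without any 1 array. That of AT5MAT had adjusted p = 0.062 and 0.065 without mock leaf replicates 1 and 3 and 0.07 without day 11 leaf replicate 3, and that of CHIL 0.054 and 0.11 without mock leaf replicates 2 and 3 and 0.078 and 0.089 without day 11 leaf replicates 2 and 3. Of 19 genes of cell division and DNA replication, 1 fell, with a median of -0.26 (adjusted p = 1.2e-06; adjusted p = 0.19 with an estimated correlation). That gene, the Aurora kinase AUR2 (AT2G25880), fell by 0.72 ± 0.17. Its adjusted p was 0.11, 0.055 and 0.19 without mock leaf replicates 1, 2 and 3, and 0.13 and 0.11 without day 11 leaf replicates 1 and 3.

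Of 4 touch-inducible genes, 1 rose, and 3 when adjusted over the list alone (adjusted p = 0.00099; adjusted p = 0.16 with an estimated correlation). Of 12 defensins and thionins, 1 rose (adjusted p = 0.018; adjusted p = 0.19 with an estimated correlation). Of 3 senescence genes 1 rose, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.065), although it did after quantile normalisation over all arrays and within organs (0.039 and 0.038), with the replicate block (0.038), and without mock leaf replicate 1 (0.034) or day 11 leaf replicate 3 (0.049). Of 27 nuclear photosynthesis genes 1 fell (adjusted p = 0.071; 0.0048 without mock leaf replicate 1 and 0.047 without day 11 leaf replicate 1). Of 9 U-box ubiquitin ligases, 2 rose (adjusted p = 0.014; adjusted p = 0.19 with an estimated correlation), and of 43 family 1 glycosyltransferases, 2 rose (adjusted p = 0.028; adjusted p = 0.51 with an estimated correlation). No single autophagy gene passed the test, with a median of 0.14 over the list (adjusted p = 0.044; adjusted p = 0.51 with an estimated correlation). No dehydration and ABA-responsive gene passed it over all probe sets and 1 fell when adjusted over the list alone, with a median of -0.42 (adjusted p = 0.018; adjusted p = 0.16 with an estimated correlation). The touch-inducible riser CML38 (1.72 ± 0.33) had an adjusted p of 0.08 without mock leaf replicate 1 and 0.055 without day 11 leaf replicate 2. The defensin PDF1.2 (1.89 ± 0.41) had 0.059, 0.067 and 0.15 without mock leaf replicates 1, 2 and 3, and 0.068 and 0.11 without day 11 leaf replicates 1 and 2. The risers were 0 without mock leaf replicate 1 and 1 without day 11 leaf replicates 2 or 3 for the ubiquitin ligases, and 0 without mock leaf replicate 1 or day 11 leaf replicate 3 and 1 without mock leaf replicate 3 or day 11 leaf replicate 1 for the glycosyltransferases. The single calls of the senescence and nuclear photosynthesis lists ended without mock leaf replicates 1 or 3 or day 11 leaf replicates 2 or 3, and that of the senescence list also without mock leaf replicate 2. Without mock leaf replicate 2 the adjusted p of the list was 0.22 for autophagy, 0.18 for dehydration and 0.084 for the ubiquitin ligases, and without mock leaf replicate 3 it was 0.12 for autophagy. Without day 11 leaf replicate 1 it was 0.28 for autophagy, 0.085 for dehydration and 0.24 for the glycosyltransferases, and without day 11 leaf replicate 3 it was 0.074 for autophagy. In all, 248 of 22746 probe sets (1.09%) changed, 164 upwards and 84 downwards, and centring each array on its median gave 218 and 65, a share of rises of 77% beside 66.1%. The count was 119 without mock leaf replicate 1, 92 without mock leaf replicate 3, 146 without day 11 leaf replicate 3, 127 with the mock and day 11 leaf arrays alone (85% rises), and 1515 with array weights (51.7% rises).

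**Figure D3:**
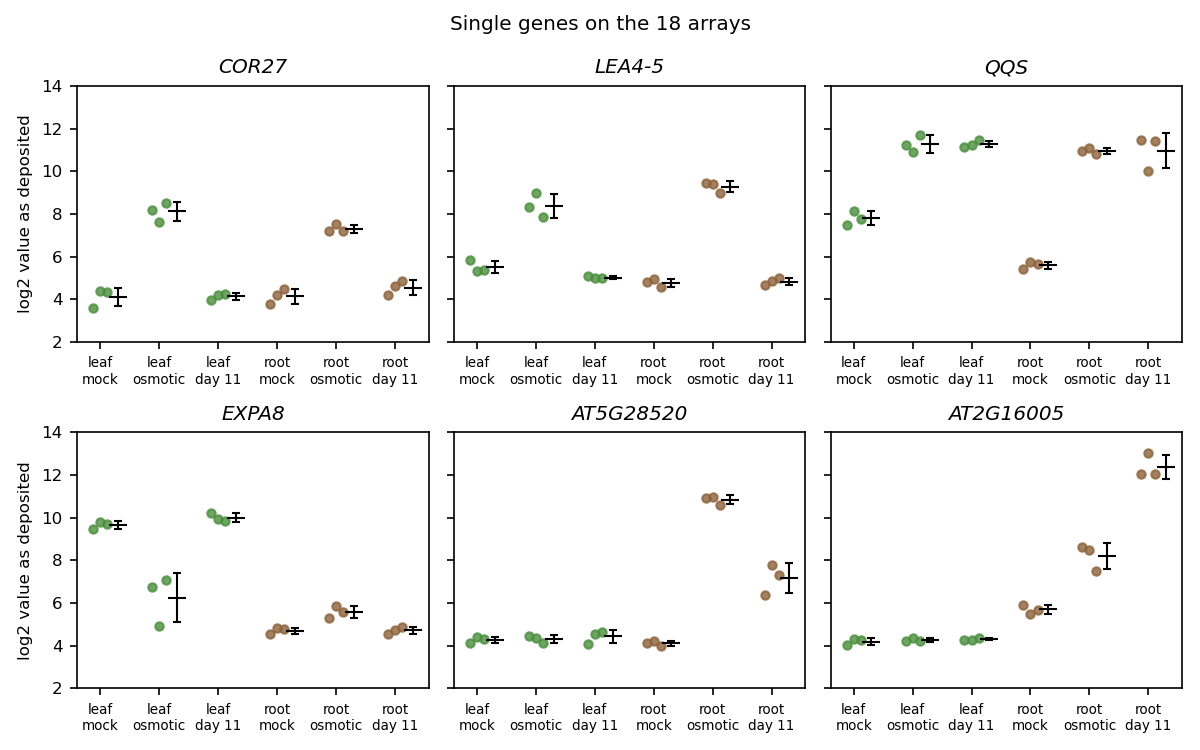
Log2 expression of COR27, LEA4-5, QQS, EXPA8, AT5G28520 and AT2G16005 on each array (points), with the group mean and SD (black), in mock, osmotic and day 11 leaves and roots, 3 arrays each. QQS stood above mock in the osmotic and day 11 arrays of both organs, and AT2G16005 reached a mean of 12.38 in day 11 roots.

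Between osmotic and day 11 leaves much of the mannitol response receded. COR27 fell by 3.98 ± 0.25 to 0.04 ± 0.25 from mock (adjusted p = 0.96), LEA4-5 fell by 3.38 ± 0.22, and EXPA8 rose by 3.76 ± 0.35. All 5 dehydration and ABA-responsive genes fell, all 5 also when adjusted over the list alone (camera adjusted p = 3.1e-11; adjusted p = 0.00049 with an estimated correlation). The senescence list fell with 2 of 3 members, 3 when adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.096 with an estimated correlation). Further lists that fell were the drought- and ABA-induced genes (5 of 14 fell and 1 rose; adjusted p = 0.0029; adjusted p = 0.096 with an estimated correlation), autophagy (5 of 10; adjusted p = 0.0012; adjusted p = 0.22 with an estimated correlation) and ER stress (7 of 13; adjusted p = 0.00018; adjusted p = 0.19 with an estimated correlation). So did branched-chain amino acid breakdown (6 of 9; adjusted p = 0.00039; adjusted p = 0.18 with an estimated correlation) and the flavonoid genes (4 of 8; adjusted p = 0.0047; adjusted p = 0.18 with an estimated correlation). Ribosome biogenesis rose with 6 of 10 members (adjusted p = 0.0002; adjusted p = 0.096 with an estimated correlation), NRPA1 by 0.93 ± 0.15. Nuclear photosynthesis rose with 5 of 27 members (adjusted p = 0.0047; adjusted p = 0.55 with an estimated correlation) and the plastid-encoded genes with 6 of 42 (adjusted p = 0.0016; adjusted p = 0.55 with an estimated correlation). These calls of nuclear photosynthesis and of the plastid-encoded genes ended without osmotic leaf replicate 2 (adjusted p = 0.12) and without osmotic leaf replicate 1 (adjusted p = 0.13), respectively. Of 11 expansins and endotransglucosylases, 4 rose and 1 fell, with the same counts when adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.19 with an estimated correlation). Without osmotic leaf replicate 2, the members past the threshold were 3 for autophagy, 3 for branched-chain amino acid breakdown, 2 for ER stress, 1 for senescence, 2 for nuclear photosynthesis and 2 for the plastid-encoded genes. They were 3 for autophagy without day 11 leaf replicates 2 or 3, 2 for branched-chain amino acid breakdown without osmotic leaf replicate 3 or day 11 leaf replicate 2, and 1 for senescence without day 11 leaf replicate 3. For nuclear photosynthesis they were 8 without osmotic leaf replicate 1 and 3 without day 11 leaf replicate 3, and for the plastid-encoded genes 3 without osmotic leaf replicate 1 or day 11 leaf replicate 1 and 12 without osmotic leaf replicate 3. The single calls against the direction of their list, in the expansin and drought lists, ended without osmotic leaf replicate 2 or day 11 leaf replicate 3.

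In all, 3888 probe sets differed between osmotic and day 11 leaves, 2077 upwards and 1811 downwards. The balance turned to 1788 upwards and 2005 downwards when each array was centred on its median, and to 359 and 486 among changes of at least 2-fold. Without osmotic leaf replicate 2 the count was 2423, and with these 6 arrays alone it was 1795. Of the 1960 that rose in osmotic leaves, 1146 (58.5%) then fell, and 87 (4.44%; 14.13 if independent) were still higher than mock. Of the 2734 that fell, 1564 (57.2%) then rose, and 42 (1.54%; 10.1 if independent) were still lower. Both steps share the osmotic arrays, and with day 11 values drawn around the osmotic means a mean of 0.1 probe sets moved back over 20 simulations, against 2710 observed (57.7% of 4694). The osmotic and day 11 changes of leaves correlated across probe sets with r = 0.3789 and rho = 0.4096, probe sets not being independent replicates. Unchanged groups simulated against the shared mock arrays gave r = 0.502, the same sign in 66.6% of probe sets (66% observed) and 0 shared calls. The covariance was 0.0143, against 0.04704 observed, larger by 0.0327. The 0 shared calls have the same limit, since no group truly differed there and the adjusted threshold let almost none pass. Part of the excess of shared calls may come from the 3 shared mock arrays, too few to split.

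The comparison of day 11 with mock roots gave a larger set of changes than that of leaves. AT2G16005, of a lipid-binding protein family, rose from a mean of 5.70 to 12.38 (6.69 ± 0.26, adjusted p = 3.6e-11), beyond its rise of 2.51 ± 0.26 in osmotic roots. QQS was higher by 5.37 ± 0.29, AT4G23680, of the major latex protein family, by 4.08 ± 0.40, the dioxygenase AT1G14120 by 3.63 ± 0.31, AT3G26460, of the same family as AT4G23680, by 3.39 ± 0.37, and the peroxidase AT5G06730 by 3.27 ± 0.37. AT5G28520 was still higher by 3.07 ± 0.25. The pectin lyase-like AT5G14650 fell by 3.46 ± 0.27 (adjusted p = 4.3e-07), AT3G55790 fell by 2.31 ± 0.41, the expansin EXPB2 (AT1G65680) fell by 2.01 ± 0.32, and PR-1-LIKE fell by 1.82 ± 0.24. The plastid-encoded genes were the 1 list past the test: 9 of 42 rose (4 without mock root replicate 1 and 3 without day 11 root replicate 2), with a median of 0.23 (camera adjusted p = 7.3e-05; adjusted p = 0.77 with an estimated correlation), ndhC by 1.18 ± 0.14. Of 27 nuclear photosynthesis genes, 1 fell (0 without mock root replicate 2 or day 11 root replicates 1 or 2) and 0 rose, with a median of -0.08 (adjusted p = 0.68). No leaf marker (adjusted p = 0.52) and no root marker (adjusted p = 0.98) passed, also when adjusted over the list alone, and the root markers had a median of -0.10, a mean of 0.07 and a test pointing upwards. The 3' minus 5' difference of the control probe sets that report RNA integrity was higher in day 11 than in mock roots for all 3 controls. It was 0.11 ± 0.10 (SD) and -0.03 ± 0.05 for ubiquitin (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), 0.228 ± 0.091 and 0.0568 ± 0.12 for GAPDH (p = 0.3), and 1.38 ± 0.10 and 1.26 ± 0.11 for actin (p = 0.3).

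In all, 1741 of 22746 probe sets (7.65%) changed in day 11 roots, 830 upwards and 911 downwards, and centring each array on its median gave 1045 and 678, a share of rises of 60.7% beside 47.7%, while the mock and day 11 root arrays alone gave 1210 and 1187. The count was 871, 966 and 1133 without mock root replicates 1, 2 and 3, 1045 and 790 without day 11 root replicates 1 and 2, and 3423 with array weights. Between osmotic and day 11 roots 4325 probe sets differed, 2311 upwards and 2014 downwards. The balance turned to 2021 upwards and 2203 downwards when each array was centred on its median, and to 593 and 812 among changes of at least 2-fold. Of the genes with the largest mannitol response, scpl30 fell by 6.06 ± 0.24, AT1G32970 fell by 5.40 ± 0.19, AT1G73600 rose by 4.21 ± 0.36 and AT1G07690 by 3.77 ± 0.19. AT5G28520 fell by 3.67 ± 0.25 but stayed above mock, and QQS stood at 0.02 ± 0.29 from the osmotic roots (adjusted p = 0.97). Of 19 cell division genes, 8 rose (camera adjusted p = 0.00013; adjusted p = 0.23 with an estimated correlation), the histone gene HTB1 (AT1G07790) by 1.16 ± 0.13. The dehydration list fell with 3 of 5 members, the same count as when adjusted over the list alone (adjusted p = 0.00061; adjusted p = 0.055 with an estimated correlation), LEA4-5 having fallen by 4.46 ± 0.22. The touch-inducible list fell with 3 of 4, the same count as when adjusted over the list alone (adjusted p = 0.0017; adjusted p = 0.22 with an estimated correlation). Early auxin response genes fell with 3 of 7, the same count as when adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.23 with an estimated correlation), the auxin-conjugating enzyme gene GH3.3 (AT2G23170) having fallen by 1.65 ± 0.20. The U-box ubiquitin ligases fell with 4 of 9 (adjusted p = 0.011; adjusted p = 0.23 with an estimated correlation), PUB24 having fallen by 1.73 ± 0.27, and 2 members fell without osmotic root replicates 2 or 3 or day 11 root replicate 1. Of 11 expansins and endotransglucosylases, 5 rose and 1 fell, or 6 and 2 when adjusted over the list alone (adjusted p = 0.035; adjusted p = 0.23 with an estimated correlation), with EXPA4 up by 1.95 ± 0.19. That call ended without osmotic root replicate 2 (adjusted p = 0.086) or day 11 root replicate 2 (0.054), and when dim probe sets were left out (0.081).

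Of the 2411 probe sets that rose in osmotic roots, 1436 (59.6%) then fell, and 409 (17%; 87.98 if independent) were still higher than mock at day 11. Of the 3112 that fell, 1511 (48.6%) then rose, and 587 (18.9%; 124.6 if independent) were still lower. With day 11 values drawn around the osmotic means a mean of 0.15 probe sets moved back, against 2947 observed (53.4% of 5523). The osmotic and day 11 changes of roots correlated across probe sets with r = 0.4924 and rho = 0.4947, probe sets not being independent replicates. Unchanged groups simulated against the shared mock arrays gave r = 0.501, the same sign in 66.7% of probe sets (69.3% observed), 0 shared calls and a covariance of 0.0143, and the observed covariance of 0.107 was larger by 0.0927. The limits given for leaves hold here for the 0.15 and for the 0 shared calls, and part of the excess of shared calls may come from the 3 shared mock arrays.

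The day 11 responses of roots and leaves were also compared directly. The response of AT2G16005 was larger in roots by 6.58 ± 0.37 (adjusted p = 1.9e-08) and that of AT1G14120 by 3.71 ± 0.44 (adjusted p = 0.0002), while the differences of AT5G14650 (mock leaf mean 3.67) and DFR (mock root mean 3.653) were limited by the background. Of 8 flavonoid genes 3 had a higher response in roots (camera adjusted p = 7.8e-06; adjusted p = 0.095 with an estimated correlation), 2 of them limited by the background. Of 19 cell division genes, 4 had a higher response in roots, with a median difference of 0.54 (adjusted p = 2.3e-08; adjusted p = 0.22 with an estimated correlation). Those 4 became 0 without mock leaf replicate 2 or day 11 root replicate 2, 1 without mock root replicates 1 or 2, day 11 leaf replicate 1 or day 11 root replicate 1, and 2 without day 11 leaf replicate 3. The 3 flavonoid genes became 1 without mock leaf replicates 2 or 3, mock root replicate 3, day 11 leaf replicate 3 or day 11 root replicates 2 or 3. No single plastid-encoded gene differed, with a median difference of 0.33 (adjusted p = 0.00051; adjusted p = 0.58 with an estimated correlation), and without day 11 leaf replicate 2 the adjusted p of that list was 0.059. In all, 520 probe sets differed, 247 with a higher and 273 with a lower response in roots. Of these, 103 were limited by the background in leaves and 13 in roots. The count was 325 and 331 without mock leaf replicates 2 and 3, 308 and 334 without mock root replicates 1 and 3, 321 without day 11 leaf replicate 3, 250 without day 11 root replicate 2, and 1274 with array weights. Of the 164 probe sets that rose in day 11 leaves, 16 also rose in roots (5.984 if independent), and of the 84 that fell, 9 also fell (3.364 if independent). The day 11 changes of both organs correlated across probe sets with r = 0.1516 and rho = 0.1865, probe sets not being independent replicates. Over all comparisons, 4 of the 53 list calls made with the preset correlation held with an estimated correlation: the dehydration, senescence and further drought lists in osmotic leaves, and the dehydration list between osmotic and day 11 leaves.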

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

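The tests of a saturated probe set, of leaf tissue among the day 11 roots, of genes at background in 1 organ and of the splits with the mean response taken out were chosen only after the result was seen, and the confidence bound in the test of the mock plants was added after its value was seen. The results of this part were picked out because the root and the leaf response differed by the interaction test, with 3513 probe sets for the osmotic and 520 for the day 11 response. Single stray arrays were not tested for in these groups of 3, although array weights were among the alternative settings.

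For the osmotic response, 4 gene lists differed between the organs (camera adjusted p = 0.042 for touch-inducible genes, 0.014 for autophagy, 0.0012 for plastid-encoded genes and 0.0023 for ribosome biogenesis), of which none passed with an estimated correlation (0.42, 0.57, 0.7 and 0.42). The touch-inducible list had an adjusted p of 0.072 and 0.06 without mock root replicates 1 and 2, 0.076 without osmotic leaf replicate 1 and 0.089 without osmotic root replicate 2. Other lists passed with 1 array left out: iron and zinc homeostasis (0.073 with all arrays) without mock leaf replicate 3 (0.041), mock root replicate 3 (0.045), osmotic leaf replicates 1 and 3 (0.048 and 0.049) or osmotic root replicate 3 (0.048), nuclear photosynthesis (0.14) without mock leaf replicate 1 (0.044), mock root replicate 2 (0.023) or osmotic leaf replicate 3 (0.049), and ER stress (0.19) without mock leaf replicate 1 (0.044) or osmotic leaf replicate 3 (0.049). Genes with a higher response in roots were AT5G28520 (6.70, adjusted p = 1.3e-09), BGLU24 (6.35), AT1G32970 (5.89), scpl30 (5.84), AT2G26380 (4.76), EXPA8 (4.3), SWEET2 (2.91), AT2G10940 (2.58), AT1G29660 (2.51), GSTU26 (2.19), AT5G44020 (1.95), BZIP61 (1.92), QQS (1.87), LEA4-5 (1.63), ARR15 (1.5), psbD (1.04) and NRPA1 (0.85). Genes with a lower response in roots were APG8A (-0.82, adjusted p = 0.011), PUB19 (-1.30), COR15B (-1.41), COR15A (-1.77), AT4G33980 (-1.97), SWEET4 (-2.10), AT3G46880 (-2.15), AT2G41190 (-2.55), PR-1-LIKE (-3.02), AT1G73600 (-3.51), AT5G01740 (-3.52), AT2G37810 (-3.55), AT4G10540 (-3.61), AT5G37450 (-3.78) and AT1G07690 (-4.02). For differences limited by the background, the value and its place in the order are set in part by it. That held in leaves for AT3G46880, PR-1-LIKE, AT5G01740, AT2G37810, AT4G10540, AT5G37450 and AT1G07690, and in roots for EXPA8, AT2G10940, AT1G29660, ARR15, psbD and RR16 (2.04). CML38 had a higher response in roots (1.45, adjusted p = 0.044), with an adjusted p of 0.1 and 0.099 without mock leaf replicates 2 and 3, 0.11 and 0.079 without mock root replicates 1 and 2, 0.086 and 0.11 without osmotic leaf replicates 1 and 2, and 0.11 without osmotic root replicate 2.

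For the day 11 response, 3 gene lists differed between the organs (camera adjusted p = 2.3e-08 for cell division, 0.00051 for plastid-encoded genes and 7.8e-06 for flavonoid genes), of which none passed with an estimated correlation (0.22, 0.58 and 0.095), and the plastid-encoded list had an adjusted p of 0.059 without day 11 leaf replicate 2. The dehydration and early auxin lists (each 0.1 with all arrays) passed with 1 array left out, dehydration without mock root replicate 2 (0.032) or day 11 root replicate 1 (0.047) and early auxin without day 11 leaf replicate 1 (0.044). Genes with a higher response in roots were AT2G16005 (6.58, adjusted p = 1.9e-08), AT1G14120 (3.71), AT4G23680 (3.69), JAL22 (3.40), AT3G26460 (3.2), AT5G06730 (3.14), AT1G30250 (1.99) and DFR (1.91). Genes with a lower response in roots were AT4G23880 (-1.77), AT4G29780 (-2.12), AT2G43590 (-2.31), EXPB2 (-2.35), AT2G25735 (-2.42) and AT5G14650 (-3.51). The background limited the differences of AT1G30250 and DFR in roots and of AT5G14650, AT3G55790, EXPB2 and PR-1-LIKE in leaves. Several calls ended when 1 array was left out. They were those of QQS (1.88; adjusted p = 0.057 without mock leaf replicate 2 and 0.054 without mock root replicate 1) and of HTB1 (0.86; 0.053 and 0.054 without mock leaf replicates 2 and 3, 0.059 without mock root replicate 2 and 0.066 without day 11 root replicate 2).

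Other such calls were those of PR-1-LIKE (-1.45; 0.057 and 0.07 without mock leaf replicates 1 and 2, 0.078 and 0.06 without mock root replicates 1 and 2, 0.051 and 0.056 without day 11 leaf replicates 1 and 2) and of ARL (-1.62; 0.067 and 0.075 without mock leaf replicates 1 and 2, 0.054 and 0.077 without mock root replicates 1 and 3, 0.076 without day 11 leaf replicate 3, 0.052 and 0.088 without day 11 root replicates 1 and 2). The call of AT1G30260 (0.85) ended with adjusted p = 0.059 and 0.065 without mock leaf replicates 1 and 2, 0.081 and 0.068 without mock root replicates 1 and 3, 0.056 and 0.076 without day 11 leaf replicates 2 and 3, and 0.066 and 0.079 without day 11 root replicates 1 and 2. The call of AT4G27654 (-2.13) ended with adjusted p = 0.1, 0.087 and 0.056 without mock leaf replicates 1, 2 and 3, 0.05, 0.11 and 0.097 without mock root replicates 1, 2 and 3, 0.051 and 0.096 without day 11 leaf replicates 1 and 2, and 0.09, 0.095 and 0.072 without day 11 root replicates 1, 2 and 3. That of AT3G55790 (-2.28) ended with adjusted p = 0.083, 0.082 and 0.097 without mock leaf replicates 1, 2 and 3, 0.074, 0.067 and 0.11 without mock root replicates 1, 2 and 3, 0.069, 0.059 and 0.1 without day 11 leaf replicates 1, 2 and 3, and 0.11 and 0.13 without day 11 root replicates 1 and 2.

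QQS stood above mock by about the same amount in the osmotic and the day 11 arrays of both organs, 3.48 and 3.49 in leaves and 5.35 and 5.37 in roots. The 4 groups levelled off at means of 10.95 to 11.28, as a saturated probe set might give. A ceiling narrows the spread between replicates, and the variance within these groups was 3.32 times that within the mock groups (95% bounds 0.37 and 16.8), but 0.901 times (0.0993 and 4.98) without day 11 root replicate 2, and 5.91 and 6.54 times without mock leaf replicates 1 and 2. Neither excludes a saturated probe set nor shows one, so the equal levels cannot be told apart from a ceiling. With a ceiling, the organ differences of QQS (1.87 and 1.88) give only that of the mock means (7.792 in leaves and 5.594 in roots). If the mock plants as a whole had differed from the others whatever the treatment, changes present at both times would be shared between the organs, and 11 of the 129 such probe sets of leaves were (8.53%, exact 95% bounds 4.33 and 14.7; 2.65 expected if independent). That share neither excludes a difference of the mock plants nor shows one, so for QQS it cannot be told apart from a lasting response to the stress. The further day of age and the transfer of the plants were not tested.

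COR27 and AT4G33980 rose in the osmotic arrays of both organs (4.02 and 3.42 in leaves, 3.17 and 1.45 in roots) and did not differ from mock by the test at day 11 (0.04 and 0.32 in leaves, 0.42 and 0.03 in roots). Both follow the time of day, and mock and osmotic plants might have been sampled at different hours, since no hour of sampling of the mock plants was given. The 9 other genes with a daily rhythm that were measured had a median absolute change of 0.19 in roots (bootstrap range 0.0508 to 1.26), with 3 of them past the threshold, and of 0.489 in leaves (0.108 to 0.82), with 4. The wide range keeps a difference in the hour open, and it cannot be told apart from a response to mannitol for these genes.

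Plastid-encoded photosynthesis genes stood above mock in day 11 roots, with a median of 0.23. A leaf share of 2.85% would raise the median plastid gene so far, and 27 nuclear photosynthesis genes by a median of 1.34. All 27 lay below their needed change, by a median of -1.29 (SD 1.13). That argues against leaf tissue among the day 11 roots as the only source, but excludes no smaller share. More transcripts of both organelles entering the labelling reaction could also raise these genes, and 16 mitochondrial-encoded genes had a median of 0.14 (SE 0.082), between no change and that of the plastid genes, so this explanation remains open. The 27 other plastid-encoded genes had a median of 0.367, with 7 past the threshold. A difference between the plants of day 10 and day 11 in age or light was not tested.

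Each comparison of 3 with 3 arrays has 10 splits of its arrays, too few for a share under 0.05. In each, only 1 of the 10 splits, the real split, gave as many changed probe sets: 4694 (highest other 2) for osmotic and 248 (28) for day 11 against mock leaves, 3888 (2) for day 11 against osmotic leaves, 5523 (4) for osmotic and 1741 (2) for day 11 against mock roots, 4325 (11) for day 11 against osmotic roots, and 12853 (0) for mock roots against mock leaves. For the organ differences 100 splits were drawn, and 3 gave as many probe sets as the real split for the osmotic (3513, highest other 7354) and 3 for the day 11 response (520, highest other 1386). These counts do not test the difference, since the split with 1386 kept the root response in full and that with 7354 held the sum of both responses. The mean response of both organs was then taken out. Only the real split now gave as many, with 3513 for the osmotic (highest other 12) and 515 for the day 11 response (highest other 1). In mixed splits the organ difference adds to the spread and lowers the counts, so chance was not excluded.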

How the results depend on the processing

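The settings of this part were fixed before any change was computed, so no test here was chosen only after the result was seen. Of 659 results of named genes past the threshold, 471 passed in every setting that applied, and none changed direction. These were picked mainly for large changes and do not describe all calls. Calls were lost by 12 and 13 after quantile normalisation over all arrays and within organs, 23 with arrays centred on their medians, 10 without the mean-variance trend, 11 with array weights, 87 with the arrays of the comparison alone and 179 with at least 1 array left out, which leaves 2 arrays in a group. Without dim probe sets (4221 left out) 655 results were tested and all passed. The cause of these changes was not tested.

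Array weights raised the day 11 counts against mock from 248 to 1515 in leaves and from 1741 to 3423 in roots. Their organ difference rose from 520 to 1274. The arrays of a comparison alone gave 3063 for osmotic and 127 for day 11 against mock leaves and 1795 for day 11 against osmotic leaves, and the cause was not tested. The stricter threshold of 0.01 gave 2685, 61, 1998, 3455, 605, 2662, 1799 and 153 for osmotic against mock, day 11 against mock and day 11 against osmotic in leaves and then in roots, and for the organ differences of the osmotic and the day 11 response. At least a 2-fold change gave 1056, 103, 845, 1684, 365, 1405 and 1666 for the first 7 of these and 6542 for mock roots against mock leaves.

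With 1 array left out, the lowest and highest counts were 3048 and 5248 for osmotic against mock leaves (3048 without osmotic leaf replicate 2), 92 and 294 for day 11 against mock leaves (119 and 92 without mock leaf replicates 1 and 3, 146 without day 11 leaf replicate 3) and 2423 and 4002 for day 11 against osmotic leaves (2423 without osmotic leaf replicate 2). In roots they were 4247 and 5160 for osmotic against mock, 790 and 1343 for day 11 against mock (871, 966 and 1133 without mock root replicates 1, 2 and 3, 1045 and 790 without day 11 root replicates 1 and 2) and 3192 and 4367 for day 11 against osmotic. They were 2655 and 3718 for the organ difference of the osmotic response, 250 and 525 for that of day 11 (325 and 331 without mock leaf replicates 2 and 3, 308 and 334 without mock root replicates 1 and 3, 321 without day 11 leaf replicate 3, 250 without day 11 root replicate 2), and 11784 and 12290 for mock roots against mock leaves. The correlation of the leaf and root osmotic changes lay between 0.364 and 0.4129 with 1 array left out and between 0.3934 and 0.3973 in the other settings.

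Of 53 list calls, 4 remained with an estimated correlation, 50 without dim probe sets, and 42 in every setting other than the estimated correlation. With 1 array left out there were 50 to 59, and 11 of the 53 were lost in at least 1 such fit, while 13 of the 181 list results that had not passed did so. The replicate numbers of the labels did not pair the arrays: in no comparison did all 3 correlations of deviations exceed 0.1 (they ran from -0.29 to 0.35), and 1 to 5 of 6 arrays correlated best with their own number. The replicate block gave 4635, 306 and 3801 in leaves, 5505, 1739 and 4309 in roots, 3485 and 580 for the organ differences, 12830 for mock roots against mock leaves, a correlation of 0.3945 and 54 list calls, and 15 gene calls were lost. Floors for dim values were not run, since they applied only to a table of linear values.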

Other observations

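No test in this part was chosen only after the result was seen, but the list member counts with 1 array left out were compiled from the planned fits after the results were seen. Several gene lists did not pass, some of them with members that changed in both directions. Of 19 sugar transporters, 2 rose and 6 fell in osmotic leaves (camera adjusted p = 0.88; median 0.05, mean -0.04, test pointing down) and 2 rose and 1 fell in osmotic roots (adjusted p = 0.37). Of 10 tau-class glutathione transferases, none passed in osmotic leaves (adjusted p = 0.88), and 3 rose and 4 fell in osmotic roots (adjusted p = 0.72). GSTU26 (AT1G17190) stood at 2.09 ± 0.15 and GSTU21 (AT1G78360) at -1.49 ± 0.17 there. In day 11 roots 2 of them rose and 2 fell (adjusted p = 0.98). Of 43 family 1 glycosyltransferases, 9 rose and 6 fell in osmotic roots (adjusted p = 0.2).

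Of 7 aldehyde dehydrogenases, 2 rose in osmotic leaves (adjusted p = 0.093) and 2 rose and 1 fell in osmotic roots (adjusted p = 0.2), with ALDH7B4 (AT1G54100) at 2.06 ± 0.17 and 2.17 ± 0.17. The fall of ALDH10A8 in roots lost its call with arrays centred on their medians (0.063), with the arrays of the comparison alone (0.053), without mock root replicates 1 and 2 (0.071 and 0.055) and without osmotic root replicate 2 (0.13), and the rise of ALDH2C4 without osmotic root replicate 3 (0.056). Of 10 chaperones, 1 rose and 1 fell in each organ (adjusted p = 0.88 and 0.79), the riser being Hop3 (AT4G12400). The fall of CLPB2 in roots lost its call with arrays centred on their medians (0.11), without the mean-variance trend (0.057), with the arrays of the comparison alone (0.096), without mock root replicates 1 and 2 (0.061 and 0.2) and without osmotic root replicates 1 and 2 (0.2 and 0.071). Of 14 genes of iron and zinc homeostasis, 1 rose and 1 fell in osmotic leaves (adjusted p = 0.73), while 5 fell in osmotic roots (adjusted p = 0.12). Of 30 endo-glucanases and other expansins, 2 rose and 5 fell in osmotic leaves (adjusted p = 0.88). In osmotic roots 2 rose and 7 fell (adjusted p = 0.72), with a median of 0.00326 and a mean of -0.15. Of 26 genes of xylan synthesis and wall acetylation, 2 rose and 4 fell in osmotic leaves (adjusted p = 0.88), and 2 rose and 5 fell in osmotic roots (adjusted p = 0.32).

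In osmotic leaves, 4 of 11 expansins and endotransglucosylases fell, the same count as when adjusted over the list alone (adjusted p = 0.074; 0.038 with arrays centred on their medians and 0.041 without osmotic leaf replicate 3). Of 19 cell division genes, 4 fell (adjusted p = 0.05; 0.047 with arrays centred on their medians, 0.04 without mock leaf replicate 1 and 0.023 without osmotic leaf replicate 1), HTB1 (AT1G07790) being at -0.61 ± 0.13. Of 7 early auxin genes, GH3.3 (AT2G23170) rose by 1.12 ± 0.20, the same count as when adjusted over the list alone (adjusted p = 0.28). Of 4 touch-inducible genes, 3 rose, the same count as when adjusted over the list alone (adjusted p = 0.095). Each of the 3 calls ended in some fits with 1 array left out: CML37 without mock leaf replicate 2 (0.069) and osmotic leaf replicates 2 and 3 (0.051 and 0.085), CML38 without mock leaf replicates 1, 2 and 3 (0.14, 0.057 and 0.054) and osmotic leaf replicate 3 (0.21), and AT1G76640 without mock leaf replicates 2 and 3 (0.14 and 0.1) and osmotic leaf replicate 2 (0.24). Of 12 defensins and thionins, 2 rose (adjusted p = 0.28). Of 8 flavonoid genes, 1 rose and 2 fell (adjusted p = 1; median -0.01, mean 0.03).

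In osmotic roots, 1 of 3 senescence genes rose, the same count as when adjusted over the list alone (adjusted p = 0.12). Early auxin genes had 1 riser of 7, or 2 when adjusted over the list alone (adjusted p = 0.18), with LBD16 (AT2G42430) at 0.90 ± 0.16. Of the 14 further drought genes 4 rose and 2 fell (adjusted p = 0.24), and of 9 genes of branched-chain amino acid breakdown 3 rose and 1 fell (adjusted p = 0.24). Autophagy had 1 riser of 10 (adjusted p = 0.37), ATG8D, whose call ended with the replicate block (0.051), without mock root replicates 1 and 2 (0.16 and 0.077) and without osmotic root replicates 2 and 3 (0.065 and 0.14). ER stress had 2 risers of 13 (adjusted p = 0.35), of which BZIP17 lost its call without mock root replicate 3 (0.057) and osmotic root replicate 2 (0.07). Risers were further 4 of 9 U-box ubiquitin ligases (adjusted p = 0.072), 2 of 10 ribosome biogenesis genes (adjusted p = 0.24; 1 without osmotic root replicates 1 or 3), 4 of 42 plastid-encoded genes (adjusted p = 0.15; 2 without osmotic root replicate 1), and 2 of 8 flavonoid genes (adjusted p = 0.072; 0.023 without mock root replicate 1), with UGT78D1 (AT1G30530) at 2.29 ± 0.20. Of 27 nuclear photosynthesis genes 2 rose and 6 fell (adjusted p = 0.22). Of 19 cell division genes 5 fell (adjusted p = 0.11), and of 12 defensins and thionins 1 fell (adjusted p = 0.37).

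In day 11 roots, 4 of 19 cell division genes rose (adjusted p = 0.055; 0.019 and 0.021 after quantile normalisation over all arrays and within organs, 0.0089 without mock root replicate 3, 0.031 and 0.025 without day 11 root replicates 2 and 3), with HTB11 (AT3G46030) at 0.62 ± 0.12. Of the other 3 calls, HTB1 ended under both quantile normalisations (0.061 each), with the replicate block (0.057), without mock root replicates 1 and 2 (0.11 and 0.17) and without day 11 root replicates 1 and 2 (0.1 and 0.19). HTB2 ended without mock root replicates 1 and 2 (0.1 and 0.072) and day 11 root replicates 1 and 2 (0.073 and 0.074), and HTB4 without mock root replicate 1 (0.056) and day 11 root replicate 2 (0.057). Of 12 defensins and thionins 2 rose (adjusted p = 0.059; 0.025 without day 11 root replicate 3), with PDF1.4 (AT1G19610) at 1.54 ± 0.34, and of 14 genes of iron and zinc homeostasis 3 fell (adjusted p = 0.077; 0.05 and a call without mock root replicate 3). Their number was 0 without mock root replicates 1 or 2 or day 11 root replicate 2 and 1 without day 11 root replicate 1, and centring on medians ended the calls of ILR3 (0.051) and bHLH34 (0.052). XTH20 (AT5G48070) rose by 1.82 ± 0.22 and GH3.3 fell by 1.09 ± 0.20, in lists that did not pass (adjusted p = 0.45 for the expansins and endotransglucosylases and 0.22 for early auxin genes, each with 2 members past the threshold, also when adjusted over the list alone).

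With 1 array left out, these counts of osmotic leaves moved by more than 1.5 times. Risers without mock leaf replicate 1 were 1 sugar transporter and 1 defensin, and fallers 3 endo-glucanases and expansins and 1 flavonoid gene. Without mock leaf replicate 2, 1 aldehyde dehydrogenase, 1 endo-glucanase, 1 xylan and 0 iron genes rose, and 2 sugar transporters, 2 expansins and endotransglucosylases, 2 cell division, 2 xylan, 1 endo-glucanase, 0 chaperone and 0 flavonoid genes fell. Without mock leaf replicate 3, 1 sugar transporter and 1 xylan gene rose, and 3 sugar transporters, 2 expansins and endotransglucosylases, 2 endo-glucanases, 1 xylan, 1 flavonoid and 0 chaperone genes fell. Without osmotic leaf replicate 1, 2 early auxin and 3 iron genes rose, and 2 xylan genes and 1 flavonoid gene fell. Without osmotic leaf replicate 2, 1 aldehyde dehydrogenase, 1 xylan and 0 iron genes rose, and 3 sugar transporters, 2 expansins and endotransglucosylases, 2 cell division, 1 endo-glucanase and 1 xylan genes fell. Without osmotic leaf replicate 3, 1 sugar transporter, 1 defensin, 1 xylan and 0 iron genes rose, and 3 endo-glucanases and 0 flavonoid genes fell.

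In osmotic roots, 1 endo-glucanase rose and 4 fell without mock root replicates 1 or 2, and 1 rose without osmotic root replicates 1 or 3. There was 1 rising sugar transporter without mock root replicate 2 or osmotic root replicate 2, 3 cell division genes fell without mock root replicate 3 or osmotic root replicate 2, and 2 chaperones rose without osmotic root replicate 1. In day 11 roots, 1 defensin rose without day 11 root replicate 2, 1 endotransglucosylase rose without mock root replicate 2, and 1 early auxin gene fell without mock root replicate 2 or day 11 root replicates 2 or 3.

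Of the lists fixed first, 6 had 1 or 2 measured members and were not tested as lists. Besides STZ, ARR15, RR16, GSTU25 and NDB2, these were the clock gene GI (AT1G22770) at 0.58 ± 0.14 in osmotic leaves (adjusted p = 0.006; 0.066 with the arrays of the comparison alone) and -0.08 ± 0.14 in osmotic roots (adjusted p = 0.74), and the Aurora kinase gene AUR1 (AT4G32830) at 0.10 ± 0.17 (adjusted p = 0.76) and -0.45 ± 0.17 (adjusted p = 0.066; 0.012 with the arrays of the comparison alone, 0.014 with array weights and 0.045 after quantile normalisation). The heat shock gene ATHSP22.0 (AT4G10250) stood at 0.23 ± 0.17 (adjusted p = 0.4) and 0.07 ± 0.17 (adjusted p = 0.8). AT5G48570, a heat-induced co-chaperone, stood at 0.76 ± 0.24 in osmotic leaves (adjusted p = 0.032), with an adjusted p of 0.2 and 0.068 without mock leaf replicates 2 and 3 and of 0.054 and 0.14 without osmotic leaf replicates 1 and 2. In osmotic leaves GSTU25 stood at 0.02 ± 0.35 (adjusted p = 0.98) and NDB2 at 0.67 ± 0.27 (adjusted p = 0.089; 0.024 without mock leaf replicate 1 and 0.028 without osmotic leaf replicate 3). The annotation named a probe set of its own for 0 members of the lists of clade A PP2C phosphatases, ABA receptors, ABA synthesis and catabolism, osmolyte metabolism, aquaporins, jasmonate, ethylene, nutrient uptake and core hypoxia genes, so nothing is said about them.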
